A study of Rattus norvegicus with 72 samples.

How the data were processed

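Gene expression was measured in the accessory lobe of the lung of 72 female Sprague Dawley rats, 1 array per rat. Per the labels' protocols, rats aged 13 weeks at the start inhaled NM-403, a multi-walled carbon nanotube, through the nose only for 6 hours a day on 5 days a week for 4 weeks, at 0.5 or 1.5 mg/m3, or filtered air, and 100 ng of total RNA per rat was labelled with Cy3 for 1-colour Agilent arrays. The images were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes.

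The deposited table holds 14687 rows of log values, 1 column per array, and all 72 columns were matched to a sample by name. The values are taken as log2, since the base is not stated: the widest range of 1 probe, 11.2, would exceed that of a scanner on a log10 scale, and a natural log is not excluded. The deposited log2 values are centred on each probe, with a median over the 72 arrays within 4.77e-07 of 0, so the level of a probe, its signal over background and the depth of an array cannot be read from them. The scaling between arrays and the direction of the values are not given in the sources used here; a higher value is taken as more RNA. Array medians lay between -0.08 and 0.10. The number of arrays limits the precision.

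Of the rows, 19 were control spots (6 named E1A, 12 named DCP and 1 bright corner spot) and 14668 probes were tested. The reference table given holds gene symbols but no probe identifiers of this array, so the files do not pair probes with genes. Probes are therefore the features, gene lists fixed before the data were examined were not run, and at most 2 rising and 2 falling identifiers are printed. The rule for named features, fixed in advance, takes the largest rises and falls at the high dose with an adjusted p under 0.05 whose 6 exposed and 6 control arrays do not overlap; it passes over probes without a symbol, which here is every probe, so identifiers are given in place of symbols and only for day 3.

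A model with 1 mean per group (12 groups of 6 arrays) was fitted to all 72 arrays with lmFit and eBayes in limma 3.58.1 under R 4.3.3, leaving 60 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probes, and a probe was called at an adjusted p under 0.05. Fixed before the data were examined were the contrasts of each dose with the controls of its day, the contrast of the doses, the change of the high-dose effect from day 3, and the controls of day 180 against day 3. Sets of probes were tested with fry and with exact two-sided permutation tests of array means, whose smallest p with 6 against 6 arrays is 0.00216. No 2 arrays correlated above 0.83, so none was treated as a repeat of another.

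The steps were tested on simulated data with 200 changed probes among 14668. For 6 exposed against 6 controls, 62.7% of probes changed by 0.5 (log2) were recovered, 97% of those changed by 1 and 100% of those changed by 2, with 13 false calls. For 6 exposed against 3 controls, 41.8% of probes changed by 0.5 and 94% of those changed by 1 were recovered, with 6 false calls. For a difference between 2 effects, 35.8% of probes changed by 0.5 and 91% of those changed by 1 were recovered. Of 200 simulated sets with no change, fry gave an unadjusted p under 0.05 for 4.5%. Simulated probes were independent of each other, which real probes are not.

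Alternatives fixed in advance were quantile normalization, equal 75th percentiles, eBayes with trend and robust settings, array weights, a fit on the arrays of the contrast only, the replicate number as a block, and a fold change of at least 1.5. All scalings were applied to the centred values. There the 75th percentile of an array depends on its spread as well as its level, so setting it equal also shifts arrays of unequal spread. The analyses added after seeing the data were the mean effects over 4 days, the sets chosen on some days and read on others, the sets chosen on 1 dose and read in the other, the same sets under 3 scalings, equal array medians, the removal of 1 array, and every analysis that divides the controls by replicate number. That division was noticed in the data: taken as trios, controls 1 to 3 resembled the high-dose arrays and controls 4 to 6 the low-dose arrays, although not every single control did. A first round of analyses gave each dose the 3 controls it resembled and took mean effects, sets and overlaps from that pairing. It was set aside, because controls picked for their likeness to an exposed group bias the comparison, and results are given with all 6 controls, with controls 1 to 3 and 4 to 6 side by side, or over all 20 divisions of the replicate numbers.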

Results

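The data set follows the lungs of rats after inhalation of multi-walled carbon nanotubes. Groups of 6 rats per exposure and time were sampled 3, 30, 90 and 180 days after exposure to filtered air, to the low dose (0.5 mg/m3) or to the high dose (1.5 mg/m3), which gives 12 groups and 72 arrays. The values are centred log2 values of 14668 unnamed probes, and each comparison below asks how many of them differed between groups, in which direction and by how much.

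The high dose was compared with the controls of the same day to ask what changed and for how long. At day 3, 321 probes differed, of which 263 rose and 58 fell. At day 30, 221 rose and 32 fell, at day 90, 352 rose and 42 fell, and at day 180, 378 rose and 128 fell. The median size of the rises was 0.60, 0.57, 0.46 and 0.50 (log2) on the successive days, and the largest rise of a called probe was 2.91, 2.61, 2.60 and 4.22. At a fold change of at least 1.5 the counts were 151, 113, 121 and 155. Among called probes, 157, 126, 144 and 189 rose with no overlap between the 6 exposed and the 6 control arrays. Chance gives such a separation, in either direction, to 0.216% of all probes. That rate is no baseline for these counts, since the probes were already called on the same arrays. The counts depended on the processing. At days 30, 90 and 180, quantile normalization gave 383 rises and 197 falls, 132 and 16, and 509 and 261. Array weights gave 923 and 754, 918 and 229, and 443 and 323 on these days. The counts also depended on which control rats were used: against controls 1 to 3 alone they were 153, 145, 80 and 88, and against controls 4 to 6 alone 579, 345, 1399 and 4048. Both trios have 3 rats, so their contrast is not one of number. A fall from the count with 6 controls may come from the smaller number alone, since 3 controls recover fewer changes. Without replicate 6 of the high dose at day 90, which stood apart in its spike-in spots, the count of that day was 158. Of the probes called with all controls, 110, 68, 62 and 72 were called in the same direction against each of these control trios, which the smaller number of controls also lowers.

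**Figure D1:**
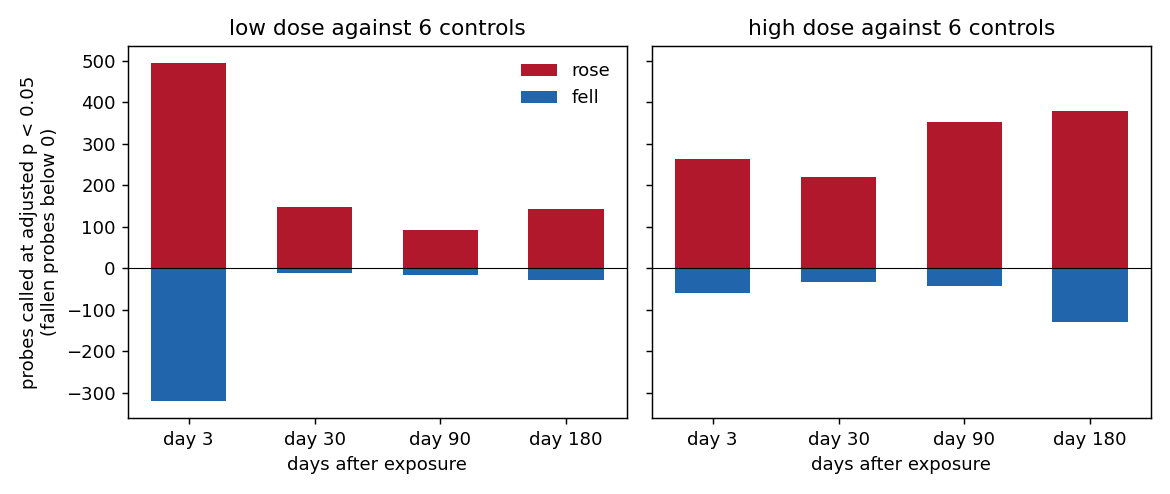
Number of probes called at an adjusted p under 0.05 for each dose against the 6 controls of the same day, with rises above 0 and falls below 0 and the days after exposure on the x axis. At the high dose on day 3, 263 probes rose and 58 fell. At the low dose on day 90, 93 rose, 78 of them in a set also high in 2 control arrays of that day, and 15 fell.

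Probes that rose at the high dose were shared between days, whose control rats differ, more often than independent lists would be. Most were called on a single day: 713 probes were called as rising on 1 day or more and 249 on 2 days or more. A probe that is not called on a day may still have risen, so these counts do not show that effects differed between days. Days 3 and 30 shared 145 rising probes where independent lists would share 3.96, days 3 and 180 shared 146 where 6.78 would be shared, and days 90 and 180 shared 141 where 9.07 would be. Falling probes shared between days numbered 4 to 10 in the 6 pairs of days, where independent lists would share 0.09 to 0.51. Falling probes were thus also shared more often than independent lists would be. In all, 98 probes rose and 3 fell at the high dose on all 4 days, and no probe rose on 1 day and fell on another. The number that rose on all 4 days was 29 against controls 1 to 3 alone and 82 against controls 4 to 6 alone, where 3 controls recover fewer changes than 6. Over the 98 probes, which were picked for these calls, the median high-dose change was 0.80, 0.72, 0.67 and 0.79 (log2), and the low-dose change was 0.69, 0.65, 0.30 and 0.58. No probe changed its high-dose effect between day 3 and a later day in limma at an adjusted p under 0.05; 187, 822 and 1057 probes had an unadjusted p under 0.05 at days 30, 90 and 180. With controls 1 to 3 alone, these tests called 0, 0 and 0 probes (limma; 260, 295 and 364 at an unadjusted p under 0.05). With controls 4 to 6 alone, they called 0, 60 and 1404 probes.

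The low dose was compared in the same way. At day 3, 495 probes rose and 320 fell, more than at the high dose, although against controls 4 to 6 alone the order of the doses was the reverse, with 147 calls at the low and 579 at the high dose. With array weights the day 3 balance turned, to 902 rises and 1298 falls. In that fit low-dose replicates 1 and 2 of day 3 had weights of 3.55 and 3.11 and the others 1.07 or less. The median change over all probes went from -0.01 to -0.035. A fit without replicates 1 and 2 was not run, so how far the turn rests on them was not tested. At day 30, 149 rose and 11 fell, at day 90, 93 rose and 15 fell, and at day 180, 143 rose and 28 fell. With array weights, which were larger in controls 1 to 3 than in 4 to 6 at day 180, that day had 3527 rises and 3086 falls. Against controls 1 to 3 alone the counts were 1880, 887, 396 and 3344, with the balance at day 90 turned to 163 rises and 233 falls, and against controls 4 to 6 alone they were 147, 56, 2 and 61. The lower counts may in part come from 3 controls in place of 6. Of the 93 rises at day 90, 78 belong to a set of at least 2-fold higher probes that was also high in 2 control arrays of that day and 2 of day 180, all among controls 4 to 6, and outside it 15 rose and 15 fell. Quantile normalization left 3 calls at day 90.

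The probe A_44_P636369 rose at the high dose at day 3 by 2.88 ± 0.29 (log2, SE, n = 6 per group; limma adjusted p = 6.92e-11), from -2.38 ± 0.57 (SD) in controls to 0.50 ± 0.35. Its rise was 2.59, 2.60 and 3.04 at days 30, 90 and 180. At the low dose it rose by 2.94, 2.78 and 2.63 at days 3, 30 and 180, whereas at day 90 the difference was 0.96 ± 0.29 and did not pass the test (limma adjusted p = 0.143). The probe A_64_P009999 fell by 1.87 ± 0.19 (SE) at day 3 of the high dose (limma adjusted p = 6.79e-11) and by 1.29, 1.50 and 2.04 on the later days. At the low dose it fell by 1.82, 1.83 and 1.88 at days 3, 30 and 180, and its difference at day 90 was -0.55 ± 0.19 (limma adjusted p = 0.241). The other 2 probes passed the test at day 3 alone among the high-dose comparisons. A_44_P505440 rose by 2.91 ± 0.62 (SE) at day 3 and its differences on the later days were 1.09, 1.77 and 1.44. A_64_P125235 fell by 0.69 ± 0.15 at day 3, with later differences of 0.14, -0.20 and -0.25. For none of the 4 probes did the change of the high-dose effect with time pass the test.

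**Figure D2:**
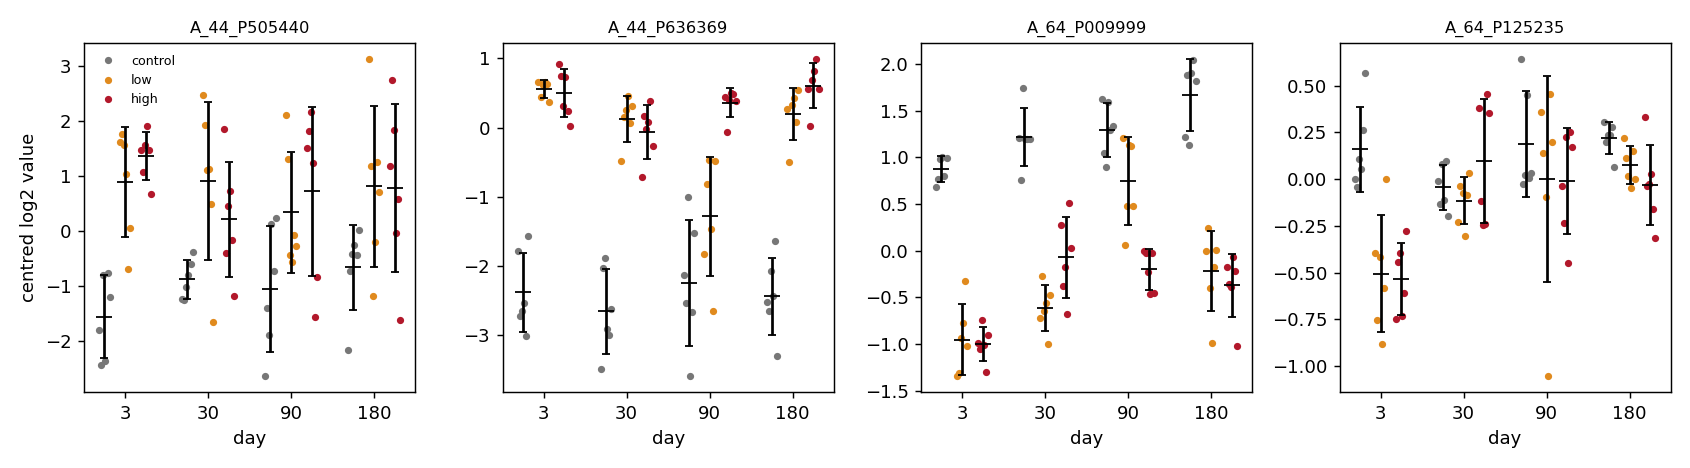
Centred log2 values of the 4 named probes in each rat by day after exposure, with points for arrays and bars for the mean and SD of 6. In A_44_P636369 the low-dose mean at day 90 is -1.28, against 0.56 at day 3.

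To read the response on arrays that did not choose the probes, sets were chosen on both doses of 3 days and read on the day left out, a step added after seeing the data. Probes that rose on the other days were higher than in controls in 6 of 6 arrays of either dose on every day, beyond the highest control (5 of 6 at the low dose of day 90 with equal 75th percentiles). The median high-dose change was 0.32 at day 3 (733 probes), 0.27 at day 30 (864 probes), 0.26 at day 90 (1081 probes) and 0.21 at day 180 (1032 probes). The low-dose change was 0.30, 0.26, 0.07 and 0.19. Each day was read in its own set of probes, so neither series measures a change with time. Each of these 8 comparisons reached an exact permutation p of 0.00216, the smallest possible, with an adjusted p of 0.00247 over 16 tests. The largest fry adjusted p of the 8 was 0.0126, for the low dose at day 90. Probes that fell on the other days had median changes between -0.28 and -0.11, with exact permutation adjusted p-values of 0.0108 or less.

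**Figure D3:**
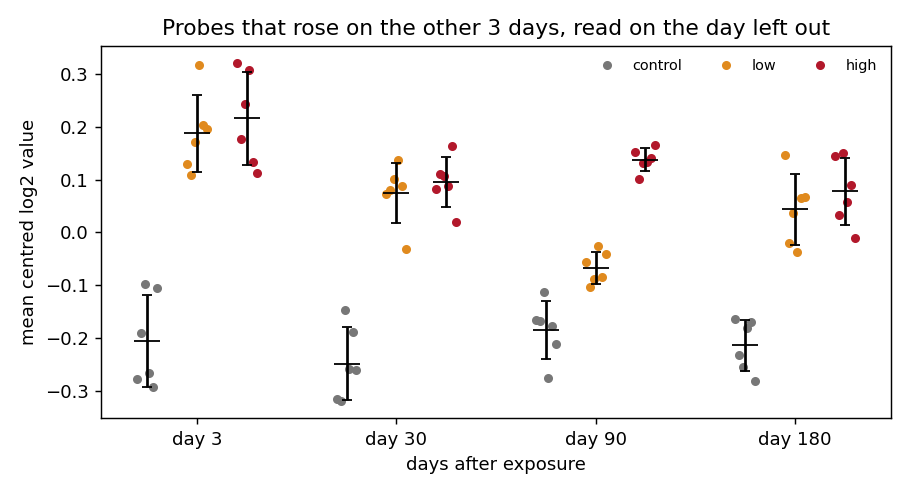
Mean centred log2 value per array of the probes that rose on the other 3 days, by day after exposure and exposure group, with bars for the mean and SD of 6 arrays. At day 90 the low-dose mean is -0.07, between -0.19 in controls and 0.14 at the high dose.

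The doses were compared with each other on each day. At day 3, 102 probes were higher and 197 lower at the high dose (2238 and 1572 with array weights), and at day 30, 92 were higher and 191 lower. At day 90 the numbers were 1926 and 426 (1357 in all without high-dose replicate 6), and at day 180 they were 2144 and 2676, far above the number by which either dose differed from its controls. The split at day 90 depended on the scaling and on the size of the difference: with equal 75th percentiles 584 were higher and 759 lower, with equal array medians 835 and 675, and at a fold change of at least 1.5 117 and 268. At day 180, equal 75th percentiles gave 3035 higher and 1968 lower, and equal array medians 2430 and 2506. In centred values the 75th percentile of an array rises with its spread, and setting it equal shifts arrays of unequal spread. The SD of the arrays at day 180 was 0.223 to 0.294 at the high and 0.327 to 0.401 at the low dose. The median of high minus low over all probes went from -0.022 to 0.055 with equal 75th percentiles. The difference between the doses at days 90 and 180 ran along a difference among the controls, which had no exposure. Of the 10 ways to divide the 6 controls of a day 3 and 3, controls 1 to 3 against 4 to 6 had the strongest correlation across probes with high minus low on all 4 days, with r = 0.54, 0.68, 0.85 and 0.85. The next division reached an absolute r of 0.52, 0.58, 0.79 and 0.64, so the lead was narrow at day 3. Probes are not independent replicates. In fits on the controls of 1 day alone, this division called 1, 0, 49 and 1875 probes (limma), and the highest count of another division was 1, 17, 1 and 54. At an unadjusted p under 0.05 it had 1212, 1271, 1338 and 4721 probes, and the highest of another division was 1723, 1727, 2153 and 867, so that it led on both counts at day 180 alone. The labels give no batch, so neither a batch term nor a within-batch value can be had, and set and dose cannot be told apart in the count.

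**Figure D4:**
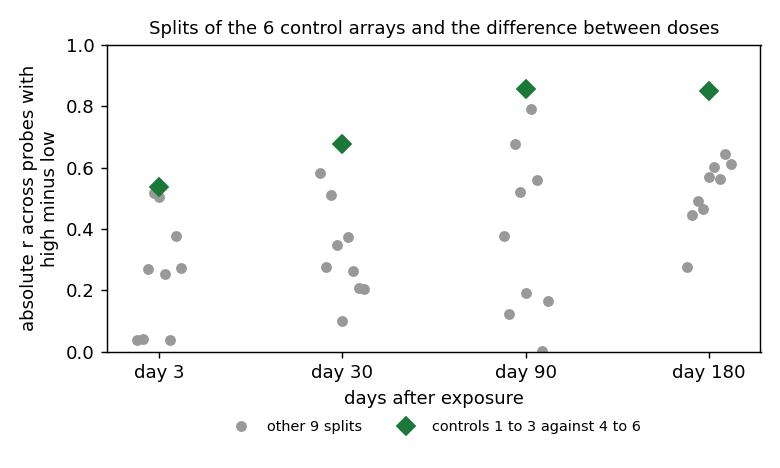
Absolute correlation across probes between high minus low and the difference of 2 trios of control arrays, for the 10 divisions of the 6 controls of each day after exposure. Controls 1 to 3 against 4 to 6 reach 0.54, 0.68, 0.85 and 0.85 and lie highest on each day.

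For the probes that rose on the other 3 days, the difference between the doses passed the test at day 90 only. The median difference, high minus low, was 0.19 at day 90 (fry adjusted p = 3.66e-06), and it was 0.03, 0.02 and 0.04 at days 3, 30 and 180, with adjusted p-values of 0.577, 0.7 and 0.577. The size of these differences depended on the scaling, of which equal 75th percentiles also shift arrays of unequal spread. In the same probes the day 90 difference was 0.13 after quantile normalization, 0.11 with equal array medians and 0.08 with equal 75th percentiles (fry adjusted p = 0.000152, 0.000763 and 0.0451), and the day 180 difference was 0.07, 0.06 and 0.11, of which the last passed (fry adjusted p = 0.0114). With sets chosen again after quantile normalization the differences at days 90 and 180 were 0.12 and 0.08, and both passed (fry adjusted p = 0.000286 and 0.0306). At day 90 all 6 high-dose arrays (lowest 0.10) lay above all 6 low-dose arrays (highest -0.03). The low-dose effect on rising probes chosen on days 30 and 180 was smaller at day 90 than at day 3, with a median change of -0.21 (fry adjusted p = 0.00115 over 12 tests), and no other change with time passed at either dose. The change of -0.21 was -0.19 under each of the 3 scalings and passed. With equal 75th percentiles the low-dose change of rising probes at day 180, -0.13, passed as well (fry adjusted p = 0.0412), and so did that of falling probes at day 90, 0.14, with equal 75th percentiles and with equal array medians.

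Probes called at both doses on a day share control rats. The numbers shared in the same direction were 208, 87, 17 and 79 at days 3, 30, 90 and 180. Independent lists would share 8.88, 2.24, 2.23 and 3.69 rising probes, where 190, 84, 16 and 75 were seen. In 50 simulations per day of unchanged groups against shared controls the shared number was 0, but no run had calls at both doses, so it sets no bound on the overlap that the differences among the controls give. When each dose was given 3 of the 6 controls, over all 20 divisions, the shared number ranged from 68 to 102, 26 to 48, 1 to 12 and 29 to 78. With 3 controls fewer changes are recovered, so the lower numbers mix this loss with the removal of shared controls. The covariance of the fold changes was 0.028, 0.013, -0.011 and -0.003, beside simulated means of 0.013, 0.012, 0.012 and 0.012, and lay below them at days 90 and 180. Their correlation was 0.551, 0.329, -0.173 and -0.051, beside simulated means of 0.477, 0.467, 0.466 and 0.487, and lay below them at day 30 as well. The spread of the simulated values was not kept. Arrays were redrawn at random, which does not keep the likeness of a control trio to a dose, so these values do not decide whether the doses agree.

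Averaged over the 4 days, an analysis added after seeing the data, 1494 probes rose and 860 fell at the high dose, and 1008 rose and 815 fell at the low dose. With array weights the low-dose balance turned, to 1814 rises and 2129 falls. The excess of rises shrank after quantile normalization, to 1403 rises and 1268 falls at the high dose and 1048 and 990 at the low dose, and equal array medians gave 1359 and 1163 at the high dose and 1134 and 850 at the low dose. Over the 20 divisions of the controls, the doses shared 309 to 403 rising probes, where independent lists would share 23.5 to 199. They shared 76 to 102 falling probes, where 3.19 to 131 would be shared, and in 1 division, with controls 4 to 6 for the high dose, the 102 seen lay below the 131. In that division 201 probes that rose at the high dose fell at the low dose and 210 went the other way. At a fold change of at least 1.5, 126 rose and 6 fell at the high dose and 118 rose and 4 fell at the low dose. With controls 1 to 3 alone the total was 1226 at the high dose and 2996 at the low dose, and with controls 4 to 6 alone 3214 and 622, the reverse order. With day 3 left out, the low-dose total went from 1823 to 626.

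Control rats themselves differed between day 180 and day 3, a comparison without nanotubes in which age, time and any difference between the arrays of the days are not separated. Of the probes, 1206 were higher and 1205 lower at day 180, and at a fold change of at least 1.5 143 were higher and 549 lower. At that fold change the excess of lower probes was smaller within the trios, with 435 higher and 505 lower in controls 1 to 3 alone and 445 and 585 in controls 4 to 6 alone. With all 6 controls, A_64_P009999 was among the higher probes, by 0.79 ± 0.19 (SE, n = 6, limma adjusted p = 0.00257).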

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

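The tests of which control trio goes with which dose, of the day 90 difference between the doses, of scaling in the low-dose change, of the bright corner spot, of the share of rises within the trios and in the mean of 4 days, and of the dose alone were chosen after the results were seen; the tests of the spike-in spots, of scaling in the counts, of the low-dose change against each trio and of random splits were written before their results were seen.

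High against low called 2352 probes at day 90 and 4820 at day 180. In the unexposed controls, the difference of 1 to 3 minus 4 to 6 correlated with high minus low at 0.849 or more on both days. This division was noticed for that likeness, and another division reached an absolute r of 0.79 at day 90 and 0.64 at day 180. The correlation thus does not decide whether the dose is the whole cause. A candidate explanation is 2 sets of arrays per day, high with controls 1 to 3 and low with controls 4 to 6. That division ranked first of 10 on 4 of 4 days, at day 3 narrowly (r = 0.54 beside 0.52 for the next). It was found in these data, and where such sets arose, in housing, dissection or array handling, is open. Subtracting the controls in that pairing leaves 0 probes between the doses on each day (limma; 265, 382, 234 and 234 at an unadjusted p under 0.05). The choice of pairing pushes this count down, and a contrast with 3 controls on each side is less precise than high minus low. The 0 thus does not show that the doses agree. The reverse pairing gives 1476, 1648, 2753 and 6393. Open too are a step from labelling on (spike-in spots, larger exact permutation p = 0.136 of high against low at days 90 and 180), a step on the array, since the bright corner spot split as the sets do at day 180 (0.32 in high-dose arrays and 0.27 in controls 1 to 3, -1.64 in low-dose arrays and -2.33 in controls 4 to 6, exact permutation p = 0.00216 for the doses) but not at day 90 (exact permutation p = 0.738), and scaling, with 40.6% of the day 90 count kept after quantile normalization and 103% of the day 180 count.

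Rises outnumbered falls against all 6 controls in the 8 comparisons with the controls as fitted without array weights. With them, low dose at day 3 had 902 rises and 1298 falls, with weights of 3.55 and 3.11 in its replicates 1 and 2 and 1.07 or less in the others. Scaling as the whole cause is argued against in these 8 by quantile normalization, after which rises made up 61.3% or more, with 3 calls left for the low dose at day 90, but it stays open in the mean of 4 days, where rises went from 63.5% to 52.5% at the high dose and from 55.3% to 51.4% at the low dose (53.9% and 57.2% with equal array medians). Sets of arrays remain open, since the lowest share of rises among comparisons with at least 10 calls was 83.7% in the pairing taken from the data, which decides nothing, and 41.2% in the reverse. At the low dose on day 90 the excess rests on 78 of 93 rises, a set also high in 4 of controls 4 to 6 at days 90 and 180 and in none (0) of controls 1 to 3. No biological explanation beyond exposure was tested.

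The probes that rose on the other 3 days were higher in high than in low arrays at day 90 (fry adjusted p = 3.66e-06), and the low-dose effect on such probes was smaller at day 90 than at day 3 (fry adjusted p = 0.00115). For high minus low, scaling remains open: in the same 1081 probes the median difference was 67.4% of its size after quantile normalization, 57.2% with equal array medians and 43.7% with equal 75th percentiles, where it still passed the test (fry adjusted p = 0.0451). Sets of arrays remain open for it too, since in the same probes controls 1 to 3 exceeded 4 to 6 by 0.07 ± 0.03 (SE, n = 3 each), 35.2% of high minus low, which was 0.20 without high-dose replicate 6 against 0.21 with it (log2). For the change of the low-dose effect, scaling as the whole cause is argued against by the same probes, which kept 88.2% or more of -0.21 and passed under 3 scalings, and the 2 sets by the control trios, with -0.24 against controls 1 to 3 and -0.19 against controls 4 to 6 (91% or more; fry adjusted p = 0.00814 and 0.0145 over 12 tests). A weaker response of these low-dose rats at day 90 than at day 3 may underlie that change, as a hypothesis found and tested on the same data, while a step that set the low-dose arrays of 1 day apart from both trios was not tested.

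In 12 groups of 6 arrays and 7 measures, 84 combinations in all, 7 had an array far from the other 5, where chance gives about 4.2. The mean of the E1A spots was 2.06 in replicate 6 of the high dose at day 90 (nearest -0.07), an array that also had the lowest array weight, 0.224, and -0.61 in control replicate 6 at day 90. The bright corner spot was -0.42 in replicate 1 of the high dose at day 180. A_44_P505440 was -2.15 in control replicate 1 at day 180, and A_44_P636369 was -0.064 in high-dose replicate 2 at day 90. A_64_P009999 was -1.02 in high-dose replicate 6 at day 180, and A_64_P125235 was -1.05 in low-dose replicate 4 at day 90.

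Random splits of the same arrays, 100 per comparison with the real one included, bear on whether chance can be excluded. The smallest share is 1 in 100 and the shares are not adjusted over the comparisons, so a low share does not exclude chance for a single comparison. For high against control, 2, 7, 9 and 1 splits at days 3, 30, 90 and 180 called as many probes as the real 321, 253, 394 and 506, and the highest other counts were 485, 959, 2114 and 48. Chance is thus not excluded for the counts at days 30 and 90 even without adjustment. For low against control, 1, 3, 4 and 11 splits called as many as the real 815, 160, 108 and 171, with highest others of 814, 383, 2260 and 2010. Even without adjustment, chance is thus not excluded at day 180. For high against low, 1, 3, 2 and 1 splits called as many as 299, 283, 2352 and 4820, with highest others of 12, 1501, 2635 and 992. Counts several times the real one point to a structure of the arrays that the groups do not name. For the change of the high-dose effect, where 0 probes were called, the splits say nothing, since all 100 reach 0 by construction (highest others 236, 252 and 299). For controls of day 180 against day 3, 1 split called as many as 2411 (highest other 1076), and for the mean of 4 days 1 split each called as many as 2354 at the high dose (highest other 1487) and 1823 at the low dose (highest other 1372).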

How the results depend on the processing

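The alternatives that divide the controls, equal array medians, the removal of 1 array or day, and all alternatives for the mean of 4 days and for sets of probes were chosen after the data were seen. No called direction of a named probe or set reversed under the alternatives run, while the uncalled difference between the doses at day 90 in probes that fell on the other days went from 0.0247 to -0.081 (log2) and passed with equal 75th percentiles. For probes that rose on the other days, the difference between the doses at day 180 went from 0.0366 to 0.0768 after quantile normalization with sets chosen again, and to 0.114 in the same probes with equal 75th percentiles, and passed in both. A fold limit keeps fewer probes, a fit on fewer arrays has fewer degrees of freedom, and a comparison with 3 controls recovers fewer changes. Array weights change which arrays count most. Beyond these, the cause was not tested where counts moved by more than 1.5 times, as follows. Quantile normalization gave 580 for high against control day 30, 148 for high against control day 90, 770 for high against control day 180, 469 for low against control day 30, 3 for low against control day 90, 1429 for high against low day 30, 954 for high against low day 90, 93 for the overlap of high day 3 and day 90, 228 for the overlap of high day 30 and day 180, 161 for the overlap of low and high day 30, 2 for the overlap of low and high day 90. Equal 75th percentiles gave 246 for high against control day 90, 1343 for high against low day 90. Array weights gave 1677 for high against control day 30, 1147 for high against control day 90, 766 for high against control day 180, 2200 for low against control day 3, 754 for low against control day 30, 241 for low against control day 90, 6613 for low against control day 180, 3810 for high against low day 3, 3267 for high against low day 30, 4072 for high against low day 90, 7351 for high against low day 180, 2 for high effect day 90 against day 3, 3660 for high against control, mean of 4 days, 3943 for low against control, mean of 4 days. At day 180 the weights were 1.34, 4.3 and 1.51 in controls 1 to 3 and 0.34, 0.423 and 0.313 in controls 4 to 6. The weighted control mean of that day thus leaned to controls 1 to 3. These alone gave 3344 calls with 55.1% rises at the low dose, beside 53.3% with weights, but 88 calls at the high dose. A fold change of at least 1.5 gave 151 for high against control day 3, 113 for high against control day 30, 121 for high against control day 90, 155 for high against control day 180, 186 for low against control day 3, 66 for low against control day 30, 84 for low against control day 180, 60 for high against low day 3, 40 for high against low day 30, 385 for high against low day 90, 950 for high against low day 180, 692 for control day 180 against day 3, 132 for high against control, mean of 4 days, 122 for low against control, mean of 4 days, 83 for the overlap of high day 3 and day 30, 76 for the overlap of high day 3 and day 90, 79 for the overlap of high day 3 and day 180, 70 for the overlap of high day 30 and day 90, 71 for the overlap of high day 30 and day 180, 66 for the overlap of high day 90 and day 180, 101 for the overlap of low and high day 3, 52 for the overlap of low and high day 30, 9 for the overlap of low and high day 90, 47 for the overlap of low and high day 180. A fit on the arrays of the contrast alone gave 166 for high against control day 3, 167 for high against control day 30, 96 for high against control day 90, 184 for high against control day 180, 208 for low against control day 3, 67 for low against control day 30, 0 for low against control day 90 (limma; 1275 at an unadjusted p under 0.05), 61 for low against control day 180, 101 for high against low day 30, 1335 for high against low day 90, 1149 for control day 180 against day 3. Equal array medians gave 1510 for high against low day 90. Controls 1 to 3 alone gave 153 for high against control day 3, 145 for high against control day 30, 80 for high against control day 90, 88 for high against control day 180, 1880 for low against control day 3, 887 for low against control day 30, 396 for low against control day 90, 3344 for low against control day 180, 1226 for high against control, mean of 4 days, 2996 for low against control, mean of 4 days. Controls 4 to 6 alone gave 579 for high against control day 3, 1399 for high against control day 90, 4048 for high against control day 180, 147 for low against control day 3, 56 for low against control day 30, 2 for low against control day 90, 61 for low against control day 180, 60 for high effect day 90 against day 3, 1404 for high effect day 180 against day 3, 622 for low against control, mean of 4 days. Leaving out high-dose replicate 6 at day 90 gave 158 for high against control and 1357 for high against low at that day. With day 3 or day 30 left out, the low-dose mean gave 626 or 1161. High minus controls 1 to 3 against low minus controls 4 to 6 gave 0 on each day, a pairing taken from the data, and the reverse gave 1476 and 1648 at days 3 and 30. Replicate numbers did not pair the rats: residuals of arrays with the same number correlated between -0.46 and 0.71, and 2, 5, 2 and 4 of 18 arrays per day correlated best with their own number. The replicate number as a block moved high against low at day 30 to 454 and no other count it was run on by as much. It was not run for controls of day 180 against day 3, the means of 4 days or the overlaps. The share of rises also moved. With array weights it went from 60.7% to 41% at the low dose on day 3, from 83.6% to 53.3% on day 180, from 93.1% to 72.4% on day 30 and from 86.1% to 65.6% on day 90, and at the high dose from 87.4% to 55% on day 30 and from 74.7% to 57.8% on day 180. Array weights also turned the low-dose mean of 4 days to 1814 rises and 2129 falls, and quantile normalization took the high-dose mean from 63.5% to 52.5% rises. Between the doses, rises went from 34.1% to 58.7% at day 3 and from 32.5% to 45.3% at day 30 with array weights, and from 81.9% to 30.4% at day 90 at a fold change of at least 1.5. With controls 4 to 6 alone the share for the high dose at day 180 was 49.8%, and with controls 1 to 3 alone that for the low dose at day 90 was 41.2%. Under other scalings the share went at the high dose from 87.4% to 66% at day 30 under quantile normalization and from 89.3% to 69.5% at day 90 with equal 75th percentiles, and at the low dose at day 30 from 93.1% to 71.4% under quantile normalization. Not run were the gene lists and the choice of 1 probe per gene, since probes have no names here, and a filter on low values, since centring removed the levels. For the same reason signal over background cannot be used to judge dim probes.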

Other observations

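The values below were chosen after the data were seen. A set of 78 probes was called and at least 2-fold higher in low-dose than in control arrays at day 90. Its mean centred log2 value was between 2.69 and 3.92 in the 6 low-dose arrays of day 90. It was also above 2 in 6 arrays of other groups, namely 2 controls at day 90, 2 controls at day 180, 1 low-dose array at day 3 and 1 at day 180, while the highest of the remaining arrays reached 0.99. The 4 control arrays were all among the 12 numbered 4 to 6, and none (0) of the 12 numbered 1 to 3 was above 2, so single rats and sets of arrays are not told apart. None (0) of the 24 high-dose arrays was above 2. Within groups these probes correlated with each other at a mean r of 0.65 across arrays.

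The bright corner control spot averaged 0.32 in high-dose and -1.64 in low-dose arrays at day 180 (exact permutation p = 0.00216, two-sided, n = 6), and 0.27 in controls 1 to 3 and -2.33 in controls 4 to 6. The averages in the same order were 0.92, 0.51, 1.00 and 0.66 at day 3, 0.25, -0.52, 0.11 and -0.71 at day 30, and -1.12, -0.96, -1.08 and -1.29 at day 90. High-dose arrays thus lay above low-dose arrays, and controls 1 to 3 above 4 to 6, at days 3, 30 and 180, although the doses did not differ past the test at days 3, 30 and 90 (exact permutation p = 0.119, 0.149 and 0.738, unadjusted). Against the controls, neither this spot nor the E1A spots differed at either dose on any day after adjustment over 16 tests (lowest adjusted p = 0.571, exact permutation).

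A set chosen on 1 dose was read in the other with separate control rats, over all 20 divisions of the replicate numbers. Probes that rose at the low dose had a median high-dose change whose middle value over the divisions was 0.31, 0.28, 0.30 and 0.23 at days 3, 30, 90 and 180, with a range at day 180 from -0.10 to 0.38. Probes that rose at the high dose had middle values of 0.20, 0.20, 0.05 and 0.16 at the low dose, with a range at day 90 from -0.09 to 0.13. Probes that fell at the low dose had middle values of -0.18, -0.09, -0.12 and -0.12 at the high dose, with a range at day 180 from -0.23 to 0.07. Probes that fell at the high dose had middle values of -0.19, -0.10, -0.11 and -0.08 at the low dose, with a range at day 180 from -0.12 to 0.15 and as few as 32.9% of probes falling. Over the divisions the sign of the median changed for falling probes on all 4 days at the low dose and on days 30, 90 and 180 at the high dose. For rising probes it changed at the high dose on days 30 (lowest -0.01) and 180 and at the low dose on days 90 and 180 (lowest -0.01).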
